A study of Gallus gallus with 4 samples.

How the data were processed

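RNA from the pre-otic domain and from the matched rostral control of the same pool of chick embryos was hybridised together on 4 two-colour Agilent arrays. Per the labels' protocols, eggs were incubated at 38 degrees Celsius, the domains were cut out with a tungsten needle, and the first somite served as the caudal limit of the pre-otic piece. Per the labels' protocols, RNA was extracted with TRIzol, cleaned on RNeasy Micro columns and amplified linearly in 2 rounds, with Cy3 or Cy5 incorporated in the last round. Amplification from so little RNA can widen or compress ratios and differs from pool to pool, which the spread between arrays includes. The labels call the arrays biological replicates, and each holds a separate pool, so both tissues of an array are paired by construction. The files show 1 slide and 1 scan date, so no slide or date could act as a batch.

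Spot values were made with Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes and the file headers. Per the file headers, the mean spot intensity and the local background intensity of each channel are not background-corrected. The processed intensity was background-subtracted, spatially detrended and dye-normalized by linear scaling and LOWESS, with surrogate values for spots at background, per the file headers. The deposited log ratio is on a log10 scale, Cy5 over Cy3, per the file headers. The series matrix deposited by the authors holds the same log10 ratios, with the sign turned on replicates 1 and 4 so that all run pre-otic over control. It differed from the turned scanner ratios by less than 0.005 at any probe, so the scale and direction of its values are settled. Each of its columns has a median of 0, which shows how the values were centred but not where the true zero lies.

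Mean and background intensities were read with R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50) on all spots, and ratios were normalized within each array by loess, in which control spots and spots with an outlier flag had a weight of 0. Loess assumes that most probes do not differ and that differences balance at each brightness, which sets the zero of every ratio. Ratios were turned to pre-otic over control by the dyes in the labels. A probe was tested if it was well above background on at least 3 of the 4 arrays in the channel of either tissue, had an outlier flag on at most 1 array and was not saturated in both channels of every array. Of 42034 probes, 27071 were tested, and 45 were left out for flags. Of the tested probes 21997 were well above background in both tissues on all arrays. Where a probe was dim on all arrays of a tissue its ratio is only a bound, which held for 19 called probes, and none of the genes named here has such a probe.

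The mean ratio over the 4 arrays was tested against 0 with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The dye effect cancels in this mean, since 2 arrays have each orientation. Probes were named through a RefSeq gene table of assembly GRCg7b, matched on accession, gene number, symbol or synonym, and no coordinates were taken from it. Of 9943 probes with a symbol, 9834 were named through the table and 109 kept the symbol of the files, and 32091 had no symbol here. Where a gene had several probes the brightest tested one stood for it; 565 genes had more than 1 tested probe, and for 0 of them limma called probes in opposite directions.

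Before the data were examined, 21 gene lists, the tests, the rule for named genes and the processing alternatives were fixed. Lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe per gene, adjusted over the 20 lists with at least 3 tested genes. Camera with an estimated correlation and fry, which tests whether a list's own genes move 1 way on balance, were run beside it. With an estimated correlation 0 of the 8 list calls held, at adjusted p of 0.19 to 0.26. The estimates were −0.092 (Notch), −0.029 (paraxial), −0.021 (heart) and −0.0009 (WNT). They were 0.079 (BMP), 0.081 (pan-placodal), 0.117 (forebrain) and 0.314 (hindbrain). This form of camera also takes its degrees of freedom from the 4 arrays alone, so a lost call need not come from correlation between genes. Named genes were the 12 largest and 12 smallest ratios among called genes with 1 sign on all 4 arrays, up to 4 called genes per list with the largest ratio in size (the 2 brightest where under 2 passed), and a fixed set of otic, hindbrain, forebrain and control genes; a few genes that the rule takes are not reported here.

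The alternatives were other background corrections, the scanner's processed signals, the series matrix, median centring, scaling between arrays, other filters on dim or saturated spots, a dye term, array weights, trended and robust variances, a separate-channel fit and leaving out each array. Gene counts without replicate 2 were added after the data had been seen. The fit was tested on simulated data with the moderated variances that limma gave for these arrays, over 27071 probes, 200 of them changed. It recovered 27 of 67 probes at 1.5-fold (40.3%), 59 of 67 at 2-fold (88.1%) and 66 of 66 at 4-fold, with 9 unchanged probes called. A simulated list shifted by 0.5 came back with a median of 0.49, and of 19 unchanged lists camera called 0. The simulated noise was independent between probes and arrays. It therefore does not test camera on lists whose genes vary together, nor the fit with an array whose ratios are compressed. Background correction was not simulated. Far fewer probes were changed than the 2129 called in the data, which affects the adjusted threshold, so the recovered shares do not carry over directly.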

Results

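Gene expression was compared between the pre-otic domain and a rostral control domain of chick embryos (Gallus gallus) at Hamburger-Hamilton stages 6 to 7. The pre-otic domain is the region from which the otic placode, the rudiment of the inner ear, will form. The control domain lay further forward and, per the series' design, could still respond to otic induction but had not been specified as otic. Which genes differ between the tissues early in inner ear development was the question set by the series title. Each of 4 two-colour Agilent arrays carried both tissues of the same pool, and each pool held 7 bilateral dissections. The pre-otic RNA was labelled with Cy3 on replicates 1 and 4 and with Cy5 on replicates 2 and 3. Of 42034 probes, 60.9%, 57.0%, 64.2% and 65.6% were well above background in the pre-otic channel of replicates 1 to 4, and 66.2%, 65.1%, 63.8% and 67.4% in the control channel. The number of arrays limits the precision of every ratio below. Ratios are log2 values of pre-otic over control with the standard error of limma's fit (SE), and each rests on n = 4 arrays unless stated.

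Among probes with a gene symbol, the genes highest in the pre-otic domain encoded a signal of the otic field, neural bHLH factors and a somite factor. FGF19, a growth factor that takes part in otic induction in the chick, was 33.3-fold higher (log2 ratio 5.06, SE 0.29, limma adjusted p = 0.00135). NEUROG1, a proneural factor, was 30.7-fold higher (log2 ratio 4.94, SE 0.13, adjusted p = 0.000358). MEOX1, a homeobox factor of the somites, was 22.8-fold higher (log2 ratio 4.51, SE 0.35). Among the genes highest in the control domain, GRP, which encodes gastrin-releasing peptide, was 30.2-fold lower in the pre-otic domain (log2 ratio −4.92, SE 0.36, adjusted p = 0.00238). HESX1, a homeobox repressor of the anterior neural plate, was 18.2-fold lower (log2 ratio −4.19, SE 0.27, adjusted p = 0.00159).

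The next genes on the pre-otic side were HES6, a bHLH factor, at 4.12 (SE 0.13), POSTN, which encodes the matrix protein periostin, at 4.11 (SE 0.35), and NDP, which encodes the FZD4 ligand norrin, at 4.10 (SE 0.23). NKX6-2, a homeobox factor of the neural tube, stood at 3.62 (SE 0.52). NPY, a neuropeptide gene, and AGRP, which encodes agouti-related peptide, stood at 3.15 (SE 0.20) and 2.16 (SE 0.13). FMOD, a matrix proteoglycan gene, was at 2.43 (SE 0.16), and the Notch target HES5 was at 2.39 (SE 0.19). PIWIL1, a piRNA-binding protein gene, was at 2.19 (SE 0.27) on its brightest probe, whereas its other, dimmer probe gave 0.09 (adjusted p = 0.620). On the control side, HHEX, a homeobox factor of anterior endoderm, was at −3.88 (SE 0.24), and GSC, a homeobox factor of the organizer and prechordal mesoderm, was at −3.78 (SE 0.46). FGB, which encodes the fibrinogen beta chain, was at −3.50 (SE 0.18), and the Wnt receptor gene FZD8 was at −3.48 (SE 0.30). LRRTM3, HS3ST2 and HKDC1 gave −3.18, −3.09 and −2.78. ARHGEF4 and CBLN2 gave −2.69 and −2.67. SH3TC1 was at −2.66 (SE 0.22) on its brightest probe and at −0.02 (adjusted p = 0.961) on the other. All 24 genes passed at an adjusted p under 0.05 with the same sign on all 4 arrays, as the rule that chose them required.

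**Figure D1:**
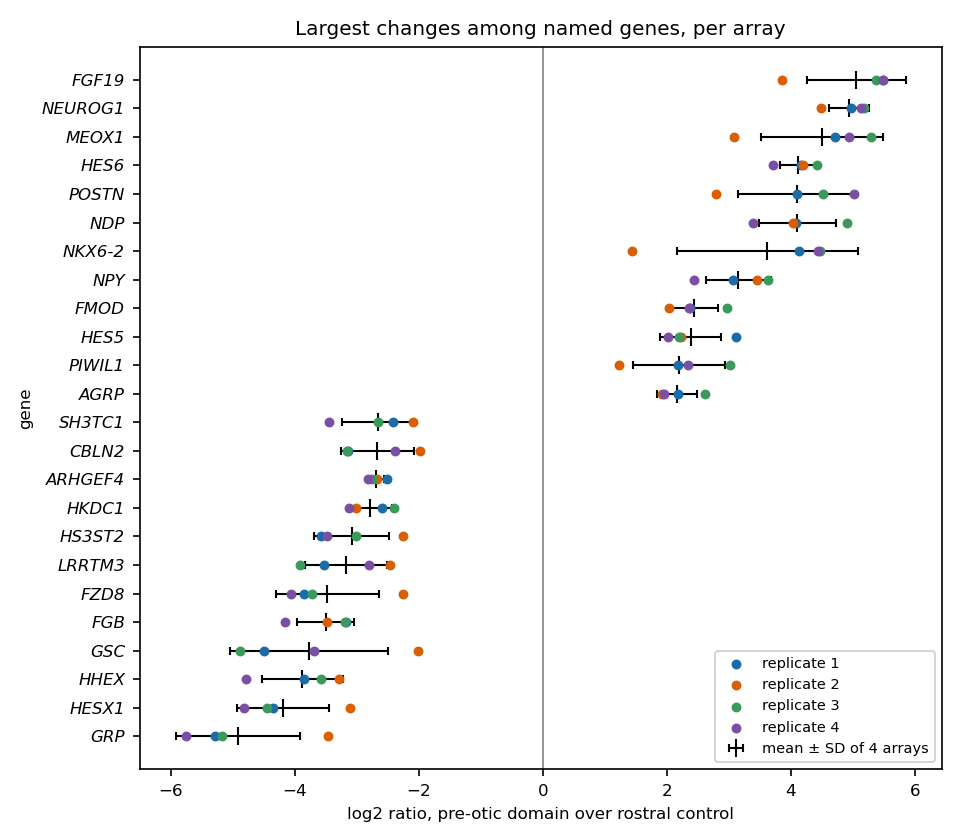
Log2 ratio of pre-otic over control (horizontal axis) for the 12 named genes with the largest and the 12 with the smallest ratio (vertical axis), as points per array, with a vertical tick and bars for the mean ± SD of 4 arrays. All 4 points of a gene lie on the same side of 0, as the choice of genes required. Replicate 2 is nearest to 0 for most genes, among them FGF19 (3.86) and NKX6-2 (1.44), but not for all (HES6, NDP and NPY are exceptions).

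Of 27071 tested probes, 738 were higher and 1391 lower in the pre-otic domain at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), so that 34.7% of calls were higher. Of these, 236 were at least 2-fold higher and 514 at least 2-fold lower, and 2120 of the 2129 had the same sign on all arrays. The counts at least 2-fold changed were 417 and 823 from processed signals, 120 higher with median centring, and 142 to 313 higher and 298 to 658 lower with an array left out. With 1 probe per gene, 201 named genes were higher and 406 lower among 6936 tested. With median centring in place of loess, 160 probes were higher and 847 lower, and 15.9% of calls were higher. Leaving out replicate 1, 2, 3 or 4 gave 198, 1069, 183 or 221 higher and 426, 1893, 391 or 504 lower probes.

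Replicate 2 stood apart from the other arrays. Across tested probes, which are not independent replicates, its ratios correlated with those of replicates 1, 3 and 4 at r = 0.414, 0.392 and 0.415, whereas those arrays correlated with each other at 0.690 to 0.713. Its log2 ratio for FGF19 was 3.86 where the others gave 5.37 to 5.50, and for NKX6-2 it was 1.44 against 4.14 to 4.46. Without replicate 2, 296 named genes were higher and 483 lower, an alternative added after the data had been seen. Of the 84 genes named by rule, 67 passed, and 35 of those passed under each of the 17 alternatives in which they were tested (SH3TC1 under 16, as it was not well above background in both channels of all arrays). The remaining 32 lost the call under at least 1. For NKX6-2, GSC, DLX5, DLX6, SIX3, SHISA2, ID3, WNT4, SFRP1, TBXT, RPL3 and CYP26C1 this took the removal of replicate 1, 3 or 4, and for the other 20 (among them PIWIL1, ETV5, TFAP2A, NR2E1, HOXA3, FGF12, ETV1, FZD10, NOG, ALDH1A3, DHRS3, TGM2, DLL1, TCF15, RIPPLY2, SHH, CDH2, PAX7 and LMO2) another setting sufficed. Taken from the series matrix, log2 ratios were over 1.5 times as large in size for SH3TC1 (−4.84), NR2E1 (−3.41), GBX2 (2.38), FZD10 (2.30), CYP26C1 (−1.97), TCF15 (1.13), ALDH1A3 (−1.12), DLL1 (0.77) and RIPPLY2 (0.67).

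**Figure D2:**
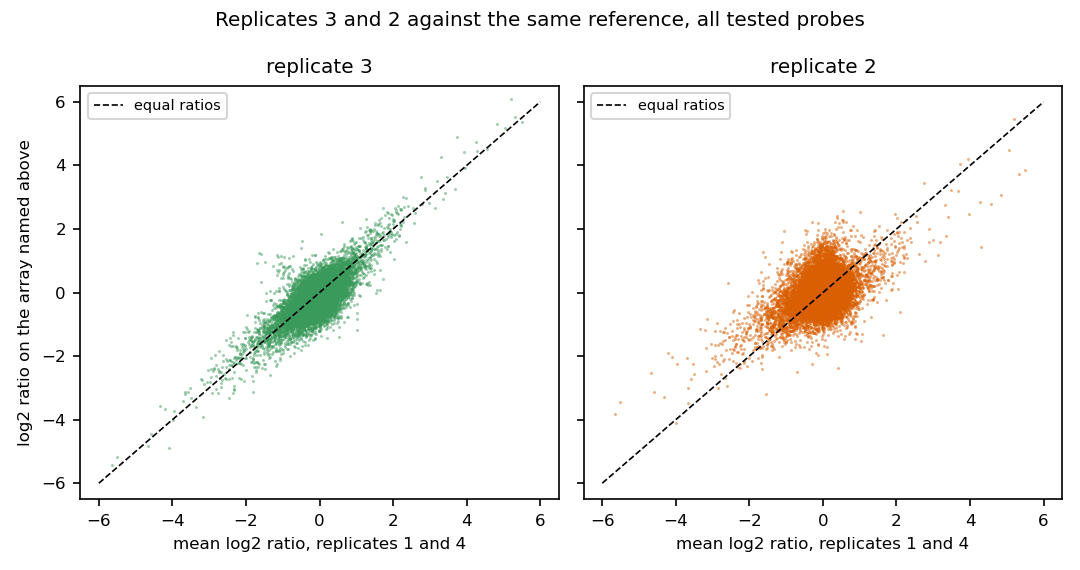
Log2 ratio of pre-otic over control on replicate 3 (left) and replicate 2 (right) against the mean of replicates 1 and 4, 1 point per tested probe, with a dashed line for equal ratios. Points of replicate 3 follow the line (slope 0.928 for probes at least 2-fold changed on the reference arrays), and those of replicate 2 spread more and lie on a flatter slope (0.579).

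Several posterior patterning genes were higher and several anterior ones lower in the pre-otic domain. In the hindbrain and posterior patterning list, 6 of 16 tested genes were higher and 10 did not pass, and 9 were higher when adjusted over the list alone. HOXA2 was at 2.11 (SE 0.14), HOXA3 at 1.69 and GBX2 at 1.56 (SE 0.16). The list's median was 0.68, and limma's camera test placed it above other genes (adjusted p = 6.64e-06; adjusted p = 0.26 with an estimated correlation). It was 0.44 without replicate 3 and 0.35 without the filter on dim probes. In the forebrain and anterior placode list, 6 of 15 tested genes were lower and 9 did not pass (7 lower when adjusted over the list alone). Beside HESX1, the eye and forebrain factors PAX6, SIX3 and NR2E1 were lower at −2.16, −1.81 and −1.73, and RAX gave −0.09 (adjusted p = 0.735). The list's median was −0.50 (camera adjusted p = 3.81e-05; adjusted p = 0.19 with an estimated correlation), and −0.26 without replicate 1.

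The otic and epibranchial placode list was not set apart from other genes by camera (median −0.01, mean −0.29, adjusted p = 0.404), while fry, which tests the list's own genes, passed (adjusted p = 0.0279). Of its 24 genes, 11 had a probe with a symbol and only 8 could be tested, so most of the list was not assessed. Of its 8 tested genes, 2 were lower and 6 did not pass, and the same counts held when adjusted over the list alone. GATA3, a zinc-finger factor later needed in the ear, was lower at −1.64 (SE 0.10), and ETV5, an FGF-responsive factor, at −0.54. PAX2, an early otic placode factor, gave 0.07 (SE 0.13, adjusted p = 0.856). The pan-placodal and non-neural ectoderm list was lower (median −0.61, camera adjusted p = 0.000344; adjusted p = 0.19 with an estimated correlation), with a median of −0.38 without the filter on dim probes. There 5 of 11 genes were lower and 6 did not pass (7 lower and 1 higher when adjusted over the list alone). PITX1 was at −2.48, DLX5 at −1.51, DLX6 at −1.49 and TFAP2A at −0.85, and DLX5 gave −0.72 on replicate 2 against −1.83 to −1.66 on the other arrays.

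Among signalling genes, FGF and WNT members went both ways, the Notch members that passed were higher in the pre-otic domain, and the BMP members that passed were lower. In the list of FGF ligands and feedback genes, 4 of 16 genes were higher, 2 lower and 10 did not pass (4 higher and 4 lower when adjusted over the list alone). FGF3, a ligand of the otic field, was higher at 1.62 (SE 0.15), as was the target ETV1 at 0.67. FGF12, an intracellular family member rather than a secreted ligand, was lower at −0.75. FGF8 gave −0.08 (adjusted p = 0.651). The list's median was −0.21 and its mean 0.23, and camera leaned downward without passing (adjusted p = 0.773). In the WNT ligands and targets list, 6 of 16 genes were higher, 2 lower and 8 did not pass (8 higher and 4 lower when adjusted over the list alone). WNT5B was at 1.78 (SE 0.14), the receptor gene FZD10 at 1.30 and the feedback gene AXIN2 at 1.06, and WNT4 was lower at −1.19. WNT8A, a candidate otic inducer, gave 0.40 (adjusted p = 0.114), and 0.27 to 0.80 over the alternatives without passing. The WNT list's median was 0.27 (camera adjusted p = 0.0173, and adjusted p = 0.19 with an estimated correlation). The median was 0.43 from processed signals and 0.13 without the filter on dim probes, and over the probes well above background in both channels of all arrays the WNT list did not pass (adjusted p = 0.070).

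In the Notch pathway list, 3 of 8 genes were higher, and 5 did not pass, also when adjusted over the list alone. HES6 and HES5 are given above, and the ligand gene DLL1 was at 0.48. The list's median was 0.14 and its mean 0.92, raised by HES6 (4.12) and HES5 (2.39). Camera placed it above other genes (adjusted p = 0.00129, and adjusted p = 0.19 with an estimated correlation). The Notch median was 0.54 from processed signals. In the BMP ligands and targets list, 5 of 12 genes were lower and 7 did not pass, with the same counts when adjusted over the list alone. MSX2 was at −1.91, BMP2 at −1.74 (SE 0.11), the inhibitory SMAD6 at −1.40 and ID3 at −1.21. The median was −0.20 (camera adjusted p = 6.46e-05; adjusted p = 0.19 with an estimated correlation). It was −0.94 from the scanner's processed signals and −1.16 over the 8 genes well above background in both channels of all arrays. The list of secreted WNT, BMP and Nodal antagonists did not pass (median −0.12, camera adjusted p = 0.491). In it SHISA2, NOG and SFRP1 were lower at −2.58, −0.86 and −0.67 and 9 of 12 genes did not pass (4 lower when adjusted over the list alone). DKK1 gave −0.57 (adjusted p = 0.0979) and passed under 2 of the 17 alternatives. CER1 gave 0.83 (adjusted p = 0.214), with 0.44 to 1.11 over the alternatives, and passed under 1.

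Retinoic acid genes went both ways. CYP26A1, which degrades retinoic acid, was lower at −1.94 (SE 0.11), and its relative CYP26C1 was lower at −0.71. TGM2, a retinoid-responsive transglutaminase gene, and ALDH1A3, a retinaldehyde dehydrogenase gene, were lower at −1.17 and −0.72, and DHRS3, a retinal reductase gene, was higher at 1.77 (SE 0.26). ALDH1A2, the main retinoic acid synthesis gene of the trunk, gave 1.25 (SE 0.29, adjusted p = 0.0587), and passed under 4 of the 17 alternatives (adjusted p 0.00253 to 0.283). Of the 11 tested genes 1 was higher, 4 lower and 6 did not pass (2 higher and 4 lower when adjusted over the list alone). The median was 0.03, the mean −0.09, and camera leaned downward without passing (adjusted p = 0.549).

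Markers of neighbouring tissues differed as well. In the paraxial mesoderm and somite list, 4 of 15 genes were higher and 11 did not pass (7 higher when adjusted over the list alone). These were MEOX1, TCF15 at 0.56, DLL1 and RIPPLY2 at 0.44, and the median was 0.25 (camera adjusted p = 0.000737; adjusted p = 0.19 with an estimated correlation). The paraxial median was 0.67 from processed signals and 0.53 with a normexp offset of 10. In the heart and lateral mesoderm list, 3 of 16 genes were lower and 13 did not pass (4 lower when adjusted over the list alone). NKX2-5, a cardiac homeobox factor, was at −2.08 (SE 0.15), ISL1 at −1.02, and BMP2, which the BMP list also holds, was the remaining one. The heart list's median was −0.24 (camera adjusted p = 0.0218; adjusted p = 0.19 with an estimated correlation). Its median on replicate 2 was −0.57 against −0.14 to −0.09 on the other arrays, and without replicate 2 it was −0.09 (adjusted p = 0.18). It was −0.37 without replicate 1, −0.14 with array weights and −0.12 without the filter on dim probes.

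The axial mesoderm and notochord list did not pass (median −0.26, camera adjusted p = 0.202). In it the notochord and primitive streak factor TBXT was higher at 1.29 (SE 0.23), GSC, SHH (−0.88) and NOG were lower, and 5 of 9 genes did not pass (1 higher and 4 lower when adjusted over the list alone). In the endoderm list, HHEX and GSC were lower and 6 of 8 genes did not pass, also when adjusted over the list alone (median −0.01, camera adjusted p = 0.475). In the blood and endothelium list, LMO2 was higher at 1.25, HHEX was lower, and 13 of 15 genes did not pass (1 higher and 2 lower when adjusted over the list alone; median −0.02, camera adjusted p = 0.530).

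In the neural plate list, HES5 was higher, CDH2, which encodes N-cadherin, was lower at −1.03, and 10 of 12 genes did not pass (3 higher and 2 lower when adjusted over the list alone). Its median was −0.03 and its mean 0.09, and camera leaned upward without passing (adjusted p = 0.761). In the neural crest and neural plate border list, GBX2 and PAX7 (1.37) were higher, MSX2 and TFAP2A were among 3 lower genes, and 7 of 12 did not pass (4 higher and 3 lower when adjusted over the list alone). The median was −0.01 and the mean 0.04, and camera leaned upward without passing (adjusted p = 0.668).

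**Figure D3:**
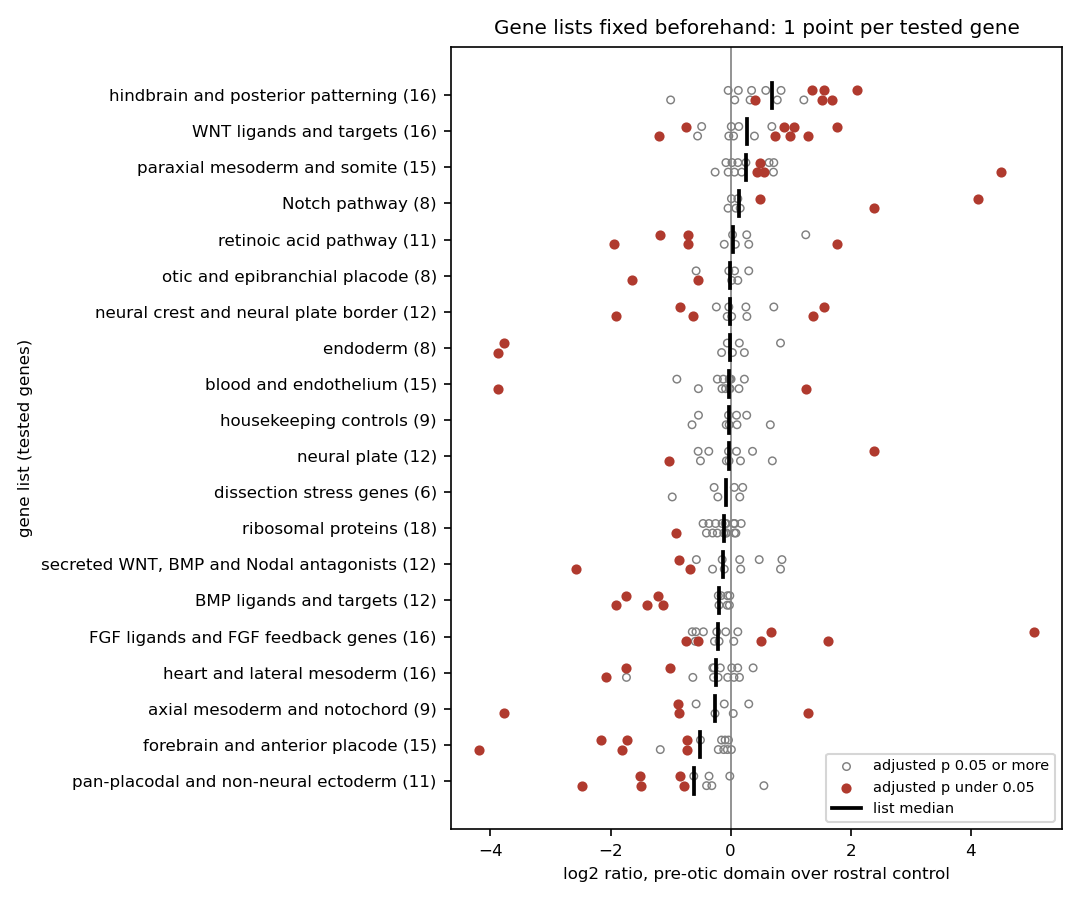
Log2 ratio of pre-otic over control (horizontal axis) of each tested gene in 20 gene lists (vertical axis, with the number of tested genes), filled at an adjusted p under 0.05, with a black bar for the list median. Medians run from −0.61 for the pan-placodal list to 0.68 for the hindbrain list.

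Medians of the control lists were near 0. None of the 6 tested dissection stress genes passed in limma, and 2 were lower at an unadjusted p under 0.05 as well as when adjusted over the list alone (median −0.08, camera adjusted p = 0.530). HSPA2 gave −0.97 on its brightest probe (adjusted p = 0.0577) and −0.90 on the other (adjusted p = 0.0202), and its brightest probe passed under 8 of the 17 alternatives (adjusted p 0.00138 to 0.3499). HSPB1 gave 0.15. The stress list's median was 0.08 on replicate 1 against −0.25 to −0.20 on the other arrays. Of 18 ribosomal protein genes 1, RPL3, was lower at −0.92 and 17 did not pass, also when adjusted over the list alone (median −0.10, camera adjusted p = 0.164). At an unadjusted p under 0.05 in limma, 4 ribosomal genes were lower and 0 higher. The ribosomal median was −0.21 without replicate 1 (camera adjusted p = 0.197) and −0.21 without replicate 3 (camera adjusted p = 0.051). None of the 9 housekeeping genes passed in limma, nor when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05 (median −0.02, mean −0.02, camera leaning upward at adjusted p = 0.757). ACTB gave −0.54 (SE 0.22, adjusted p = 0.242, and −0.79 to −0.32 over the alternatives), GAPDH −0.02 and UBB 0.11. Of the 13 W-linked genes listed, HINTW alone had a probe with a symbol. It gave −0.04 (limma adjusted p = 0.951), from −0.81 on replicate 1 to 0.41 on replicate 3.

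RPL32, RPLP1 and UBB, among the brightest genes, took the sign of the dye orientation on each array. RPLP1 gave −1.32 and −0.90 on replicates 1 and 4 and 1.58 and 0.89 on replicates 2 and 3, for a mean of 0.06, and RPL32 had a mean of −0.07. With a dye term in the model, limma called 0 probes for the dye at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1531 of 27071, a share only slightly above the 0.05 that chance alone gives. Among the genes to be named whatever their values, PAX8, FOXI3, EGR2, HOXB2 and OTX2 were not analysed here, and the HOXB1 probe was too dim to be tested.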

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

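The comparisons of replicate 2 with a mixing curve and with heart markers were chosen only after the result was seen. The 4 values of each of 84 named genes, 20 gene lists and 7 array measures were searched for an array whose gap to the nearest other, as a share of the whole range, exceeded Dixon's 95% critical value. Of these 111 groups 6 held such an array, and chance gives about 1 in 20.

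Replicate 2 was the array in 5 of the 6. Its mean correlation with the other arrays was 0.407, against 0.592 to 0.607 for the rest. FGF19 had a log2 ratio of 3.86 on replicate 2 against 5.37 to 5.50 elsewhere, NKX6-2 1.44 against 4.14 to 4.46, and DLX5 −0.72 against −1.83 to −1.66. The median of the heart and lateral mesoderm list was −0.57 on replicate 2 against −0.14 to −0.09. The remaining case was the dissection stress list, with a median of 0.080 on replicate 1 against −0.25 to −0.20 on the other arrays.

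Weaker signal on replicate 2 is argued against as the whole cause of its low correlation: over the 6768 brightest probes its mean correlation was still 0.209 below that among the other arrays (0.525 against 0.734), after 0.292 over all tested probes. Partial mixing of each tissue of replicate 2 with the other would compress its ratios, which ran at 0.555 to 0.601 of those of reference arrays (0.886 to 0.974 for the third array), and the best curves would need 16.1% to 18.8% of the other tissue. Such shares are argued against as the whole cause, since even the lowest allows log2 ratios of at most 2.38, while 8.70% of 92 probes beyond it on the other arrays passed it by over 2 residual SDs on replicate 2 (2.28% by normal scatter, exact binomial p = 0.00123 with probes taken as independent), among them NEUROG1 at 4.49 and HES6, not compressed, at 4.20; the compression stays unexplained. More heart mesoderm in its control tissue stays open: the heart list's shift on replicate 2 lay at percentile 22.6 of 10000 random lists of the same size and signal, with TNNT2 2.77, ACTA2 1.93 and MYL2 1.55 below the mean of the other arrays, but the brighter MYL3 and TNNC1 only 0.11 and 0.31 below, BMP2 level with it, and ISL1 and NKX2-5 0.25 and 0.36 above (all chosen after their values were seen). No biological explanation was tested, since the design names no difference between pools.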

How the results depend on the processing

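The gene counts without replicate 2 and the counts under turned signs were chosen only after the result was seen. No called result changed direction under any alternative run, while the medians of 8 lists that did not pass crossed 0. The cause of the changes below was not tested. Leaving out an array lowers the number of arrays fitted and also unbalances the dye orientations, so that the dye effect no longer cancels. Probes higher and lower numbered 160 and 847 with median centring, 298 and 761 with trended and robust variances, 1567 and 2389 in the separate-channel fit, and 208 and 447 at an adjusted p under 0.01. At least 2-fold higher were 120 with median centring, 417 from processed signals and 416 from the series matrix, and 823 were at least 2-fold lower from either source. Leaving out an array gave 183 to 1069 higher, 391 to 1893 lower, 142 to 313 at least 2-fold higher and 298 to 658 at least 2-fold lower probes. Without replicate 1, 3 or 4, 624, 574 and 725 probes were called, and without replicate 2, 2962, of which 1917 were shared with the 2129; named genes then numbered 296 higher and 483 lower.

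With an estimated correlation no list passed: the medians of −0.61 (pan-placodal), −0.50 (forebrain), 0.27 (WNT), −0.20 (BMP), 0.14 (Notch), 0.25 (paraxial) and −0.24 (heart) had an adjusted p of 0.19, and 0.68 (hindbrain) 0.26. WNT (0.27) did not pass among probes above background in both channels either (adjusted p = 0.070). The heart list ranged from −0.370 to −0.087 with an array left out (adjusted p 0.00789 to 0.176). With fry, the 8 lists that camera called at its preset correlation passed as well, at adjusted p of 0.0014 (Notch) to 0.028 (hindbrain). So did lists that camera did not call: otic (−0.0063), FGF (−0.21), retinoic acid (0.032), endoderm (−0.0125) and ribosomal (−0.10) genes. Of 1426 values of single genes under alternatives, 145 lost the call and 15 gained it, and of the losses 27, 29 and 28 came without replicate 1, 3 or 4 and 18 with median centring. The 4 arrays allow 8 sets of signs, the real one included, too few for a share under 0.05; the real signs gave 2129 calls, reached by 1 set (the real one), and the highest of the others was 0 (limma; 519 to 2416 at an unadjusted p under 0.05). No slide block was run, since there is 1 slide. No further pairing was run, because each ratio already pairs the tissues of 1 pool and there is 1 group of ratios. Of 14963 probes that were not tested, 45 were left out for flags and the rest for signal near background.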

Other observations

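The genes of the next paragraph were chosen after their values were seen, and the tests on the 2-fold calls, on dim probes and on saturated spots were chosen only after the result was seen.

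EDNRB, an endothelin receptor gene, was 4.38-fold higher in the pre-otic domain (log2 ratio 2.13, SE 0.10, limma adjusted p = 0.00109), and the gene of its ligand EDN3 was higher at 0.82 (adjusted p = 0.00769, kept under 15 of 17 alternatives). CHRDL1, a BMP-binding protein gene, was at 2.02 (SE 0.19) and PDGFA, a growth factor gene, at 1.91 (SE 0.12), both kept under all 17. CXCL14, well above background in the control channel of only 1 array, was at 1.62 (1.34 to 4.07 over the alternatives) and DACT2 at 1.29 (each kept under 13), CNTN2 at 1.52 (15) and the zinc-finger factor SP9 at 1.25. SST1 (somatostatin) was lower at −2.64 (kept under 16), CCK at −1.97 and TAC1 at −1.68 (14 each) and HCRT at −0.91 (12). FGG, which encodes another fibrinogen chain, was lower at −2.49 beside FGB, and the homeobox gene NKX2-6 was lower at −2.07. RELN, LMO3 and MAB21L1 were lower at −2.11, −1.95 and −2.14, each kept under all 17 alternatives.

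Many of the probes that differed have no gene symbol here: 533 were higher and 980 lower. They made up 11 of the 24 probes with the largest change in size, led by A_87_P015448 at 5.49 (SE 0.17) and A_87_P032184 at −5.13 (SE 0.32).

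More probes were lower than higher in the pre-otic domain, 1391 against 738. A constant of 0.09 added to every log2 ratio would even the calls, so the centring of the ratios may account for the imbalance among all calls and stays open, although median centring made it larger (15.9% higher, after 34.7% with loess). For probes at least 2-fold changed the constant was 0.20, and centring stays open there too, because each normalization tried sets the centre of all probes near 0 and so could not show a misplaced zero. Probes dim in 1 tissue are argued against as the whole cause, since 34.8% of calls were higher among probes well above background in both channels of all arrays. That filter kept 1907 of the 2129 calls, so it could move the share only a little and does not measure a smaller part. The difference between the tissues themselves stays open and was not tested apart from these.

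Ratios of the brightest probes followed the dyes more than the tissues. Of the 271 brightest tested probes 45.8% (95% Wilson interval 39.9% to 51.7%) had the same Cy5 over Cy3 sign on all 4 arrays, against 10.3% of the others and 12.5% by chance, and 123 of them were brighter in Cy5 on every array, which is consistent with a dye bias at the top of the signal range. The Wilson intervals here take probes as independent, although all share the same 4 arrays, so they do not measure the spread between arrays. Saturation is argued against, since 0.738% of the spots of the brightest probes (8 of 1084) were saturated. With median centring, which uses no loess curve, 50.6% of these probes had a constant dye sign. Their median log2 ratio of Cy5 over Cy3 was then 0.68, after 0.30 with loess. These values argue against the loess curve as the source of the dye bias at these probes. In the scanner's processed signals that median was 0.05, and 23.99% (19.3% to 29.4%) had a constant dye sign. This interval spans the 20% set for the test, so whether loess left bias that the scanner's normalization removes stays open. The swap cancels such a bias in the mean but widens the error, and 2.95% of these probes were called, against 7.91% of the others.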
